A study of Mus musculus with 3 samples.

How the data were processed

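Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on dorsal epidermis of wild-type mouse embryos at E18.5. The 3 libraries were an input without antibody, an HDAC3 precipitation (Abcam ab7030) and a KLF4 precipitation (R&D AF3158), per the labels. They were grouped by the antibody in the labels, 1 library per group. A peak list for each precipitation was analysed; the input entered only through the values the lists give for it.

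Per the labels' protocols, chromatin from fixed epidermis was sonicated and incubated with antibody before libraries were made with Illumina adaptors. Per the submitters' processing notes, bcl2fastq, STAR and HOMER were used with the mouse genome GRCm38.p5; versions of these tools are not given in the sources used here. Per the file headers, peaks were called in HOMER's factor style, separately for each precipitation and with no pooling, each against the same input. Peaks had a fixed width of 185 bp and a minimum spacing of 370 bp, and the fragment lengths used were 160 bp for HDAC3 and 168 bp for KLF4. Per the file headers, a peak needed at least 4-fold more tags than the input and than the surrounding 10 kb, a Poisson p-value of 1e-04 over the input and a false discovery rate of 0.001, with an effective genome size of 2000000000 bp. Of 315415 putative HDAC3 peaks, 63.2% were removed against the input and 58228 peaks against the local region; for KLF4 these figures were 63.3% of 205931 and 28389.

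Each list gives several values per peak in different units. The deposited tag signal is a tag number normalised by the authors to a common library size, and 2 further tag columns give the tags scaled to the input and the input tags, where an input of 0 is written as 0.5. The authors' score is the caller's position-adjusted tag number, and it was used only to describe and rank peaks within a list. The fold over input and the fold over the local region are ratios computed by the authors' caller. The p-value of each peak over input and over the local region comes from the authors' caller and was not used in any test here. The focus ratio, a fraction between 0 and 1 in the deposited lists, was read and not analysed further. No column was of a kind that could be assigned to a replicate.

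The HDAC3 library held 56787485 tags and the KLF4 library 61432711 tags, per the file headers. The input total implied by the scaling in the lists corresponds to 2.57 input tags per peak width under an even spread. An input number this low is imprecise for a single peak. Intervals on shares are exact Clopper-Pearson intervals at 95%. They cover counting error alone, because PCR copies are not independent molecules and no second library of either factor was analysed.

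Peaks were placed on a gene table of GRCm38.p6 that lists 49943 genes, 21887 of them protein-coding, with start and end but no strand. Patch releases leave the coordinates of the primary chromosomes as they are. As a check, the ends of protein-coding genes were moved by 10 and 50 kb in each direction: the share of peaks within 1 kb fell from 6.97% to between 4.33% and 4.55% for HDAC3 and from 10.8% to between 5.29% and 5.68% for KLF4. Because transcription start sites could not be told from transcript ends, the promoter of the intended design was replaced by either annotated gene end within 1 kb. Peaks on unplaced contigs were left out of the comparisons with genes and of the overlap of the whole lists with placements. The observed shares per decile and the comparison of scores include them, while the placement means per decile leave them out and rest on 100 placements. No genome sequence was used here, so 21 planned motif searches and the random gene lists matched on GC content were not run.

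A pair of peaks overlapped when their centres were at most 184 bp apart, which is an overlap of at least 1 bp. The share of overlapping peaks was set against 1000 random placements in which every peak of the other list moved to another random protein-coding gene end of the same chromosome class (autosome, X or Y) while keeping its distance and side; p is two-sided. Peaks were ordered by score into 10 deciles within each list. To bound what the shared input can do, the Poisson probability that an input at its mean passes the 4-fold rule was computed for each peak. Its inverse is the largest factor by which the same input could raise chance overlap if input were evenly spread. The mean of that factor over the peaks of a decile is given. Heights of shared and unshared peaks were compared as the share of all pairs in which the shared peak scored higher.

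A gene carried a factor when a peak centre lay within 1 kb of either end. The association between the factors across genes was tested with Fisher's exact test and set against every rotation of one set along the gene order. A total of 23 gene lists had been fixed: cornified envelope and late differentiation, spinous layer and Notch, basal layer and hemidesmosome, epidermal transcription factors, the HDAC3 corepressor complex, other class I deacetylase complexes, barrier lipid synthesis, desmosome and tight and adherens junctions, hair follicle placode, cell cycle, p53 targets, nuclear receptor targets, circadian clock, immediate early genes, keratinocyte inflammation, ribosomal proteins, developmental regulators of other lineages, and markers of melanocytes, Langerhans and T cells, dermal fibroblasts, skeletal muscle, liver and neurons. Of 504 distinct names in them, 500 matched the gene table, and some genes such as Ovol1 stand in more than 1 list. Each list was compared with all other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 46 tests and a threshold of 0.05. The odds ratio was computed with 0.5 added to each cell where a cell was 0.

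Genes named in the text followed a rule. It took the 10 protein-coding genes with the highest gene-end peak of each factor, the 10 with the lowest sum of ranks of both factors, up to 4 members of each list ranked by their best assigned peak, and 14 regulators and layer markers that were examined with or without a peak. Every peak was also assigned to the protein-coding gene of the nearest end. Hopx, Grhl2, Elf3, Twist2, the genes beside strong unshared peaks and individual microRNA genes fall outside that rule and were chosen after their values were seen. A gene's listed score is that of its highest peak within 1 kb of an end unless a distance is given.

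The alternatives tried were an overlap of at least 93 bp, centres within 100 bp, the higher-scored 50% of each list, peaks at least 8-fold over input, uniform placement within the chromosome, a 5 kb window, ends of protein-coding genes only, and any peak nearest to the gene. Others were added after seeing the data: the 10000 highest peaks of each list, peaks that would pass the 4-fold rule at 3 times the expected input, rotations of the lists along the gene order, and 10000 random lists matched on the number of protein-coding gene ends within 50 kb in 10 bins. Leaving out a replicate, splitting the samples and a paired comparison had no meaning with 1 library per antibody.

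The procedures were tested on simulated data. Planted overlaps of 0, 2, 10 and 30% of 57920 HDAC3 peaks came back as 0.0722, 1.80, 9.74 and 29.4 percentage points above the placements. The simulated KLF4 peaks came from the same placement procedure as the comparison. Their recovery therefore checks the computation and cannot show that the placements suit real peaks. Simulated lists over 21887 genes were called in 0% of cases at a true odds ratio of 1. At a true odds ratio of 3 they were called in 57.0% for HDAC3 and 55.4% for KLF4, and at 5 in 85.0% and 89.8%. Each rate is for lists that all had the same true odds ratio. A mixture of enriched and unenriched lists, as in the real adjustment, was not simulated, so the real detection rates may be lower. The 0% does not cover lists whose genes lie side by side and can share a peak. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.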

Results

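Chromatin occupancy of HDAC3 and KLF4 was profiled in the skin epithelium of mouse embryos shortly before birth, when the epidermis completes its outer barrier. HDAC3 is a class I histone deacetylase that works within corepressor complexes, and KLF4 is a zinc finger transcription factor needed for formation of the skin barrier. Dorsal epidermis of wild-type embryos at E18.5 gave 3 libraries: 1 precipitated for HDAC3, 1 precipitated for KLF4 and 1 input library of chromatin without antibody. The HDAC3 library held 56787485 tags, of which 3.95% lay in its 57936 deposited peaks. The KLF4 library held 61432711 tags, of which 6.81% lay in its 47155 deposited peaks. Both lists had been called by the authors against the same input, which an even spread would leave with 2.57 tags per peak width. With 1 library per antibody there was no replicate spread, so no difference between the libraries was tested, and the intervals on shares are exact Clopper-Pearson intervals at 95% that cover counting error only.

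Where each factor sat relative to genes was described first. Of the HDAC3 peaks on chromosomes, 11.4% (11.2 to 11.7; 6620 of 57920) were centred within 1 kb of an annotated gene end, 52.1% lay elsewhere inside a gene and 36.5% lay between genes. The KLF4 list had 16.0% (15.7 to 16.3; 7533 of 47140) at gene ends, 51.6% inside genes and 32.4% between genes. Positions drawn uniformly on the same chromosomes fell at gene ends in 6.41% of cases for either list, so gene ends carried 1.78 times as many HDAC3 peaks and 2.49 times as many KLF4 peaks as uniform positions. A gene end here was either annotated end of a gene, because the gene table used gave no strand, and transcription start sites could not be told from the other ends. The shares depended on that definition: with ends of protein-coding genes alone they were 6.97% for HDAC3 and 10.8% for KLF4, and within 5 kb of any gene end 33.6% and 40.9%.

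Peak heights differed in their distribution within the lists. The score, a tag number assigned to each peak by the authors' caller and used here only to rank peaks within a list, had a median of 22 for HDAC3 (quartiles 18 and 32, maximum 245) and 65 for KLF4 (quartiles 40 and 107, maximum 824). The median enrichment over input was 6.85-fold for HDAC3 and 8.60-fold for KLF4. Many HDAC3 peaks stood just above the calling limit: 44.4% were within 4 tags of its threshold of 16 tags, against 6.01% of KLF4 peaks within 4 tags of a threshold of 19. The strongest HDAC3 peak of the genome, at chromosome 8, 106563980 to 106564164 (GRCm38), lay 7161 bp outside Cdh3, which encodes the P-cadherin of basal keratinocytes; it scored 245, was 47.0-fold over input and had a KLF4 peak of score 390 centred 25 bp away. The strongest KLF4 peak, at chromosome 5, 114687958 to 114688142, lay 2885 bp inside Gltp, a glycolipid transfer protein gene, scored 824 and had no HDAC3 peak nearer than 4035 bp.

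Whether HDAC3 occupied the sites of KLF4 was the central question. Of the HDAC3 peaks, 25.8% (25.5 to 26.2; 14962 of 57920) overlapped a KLF4 peak by at least 1 bp, and 31.7% of KLF4 peaks (31.3 to 32.2; 14962 of 47140) overlapped an HDAC3 peak. The pairs were tightly superposed: their centres were a median of 31 bp apart (quartiles 14 and 59 bp), and 69.5% were within 50 bp of each other. At Rbbp8, a gene of DNA end resection, both factors had a peak at exactly the same interval, chromosome 18, 11633140 to 11633324, 44 bp outside a gene end. When KLF4 peaks were moved to other protein-coding gene ends at their own distances, a mean of 1.07% of HDAC3 peaks overlapped one (highest of 1000 placements 1.19%), which put the observed share 24.2 times above that mean (two-sided permutation p = 0.002, the smallest the 1000 placements can give). The reverse placement gave a mean of 1.67% (highest 1.85%), a ratio of 19.0 and the same p.

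Overlap with KLF4 was concentrated in the higher HDAC3 peaks. In the highest score decile of the HDAC3 list, 86.6% of peaks (85.7 to 87.4; 5016 of 5794) overlapped a KLF4 peak, then 70.7% and 46.5% in the next deciles, and 2.0% (1.66 to 2.40; 116 of 5793) in the lowest. Random placements gave means of 1.69% in the highest and 0.625% in the lowest of those deciles. The KLF4 list showed a shallower gradient, from 68.5% (67.1 to 69.8; 3229 of 4716) in the highest decile to 9.80% (8.96 to 10.7; 462 of 4715) in the lowest. Both lists shared an input library, which could raise chance overlap. An upper bound on that factor came from a Poisson calculation at an even spread of input. Its mean was 1.0 in the highest HDAC3 decile, 1.85 in the lowest and 1.94 in the lowest KLF4 decile. Input was not evenly spread: peaks of the highest HDAC3 decile averaged 5.88 input tags, against 2.57 for an even spread. Shares moved by more than 1.5 times under some choices of peaks: among the 10000 highest peaks of each list they were 49.1% for HDAC3 and 49.0% for KLF4, and among peaks at least 8-fold over input the KLF4 share was 20.4%. With that cut on both lists, the HDAC3 share was 21.7%, against 25.8% for the whole list. The gradient above is by score and was not shown for fold over input.

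**Figure D1:**
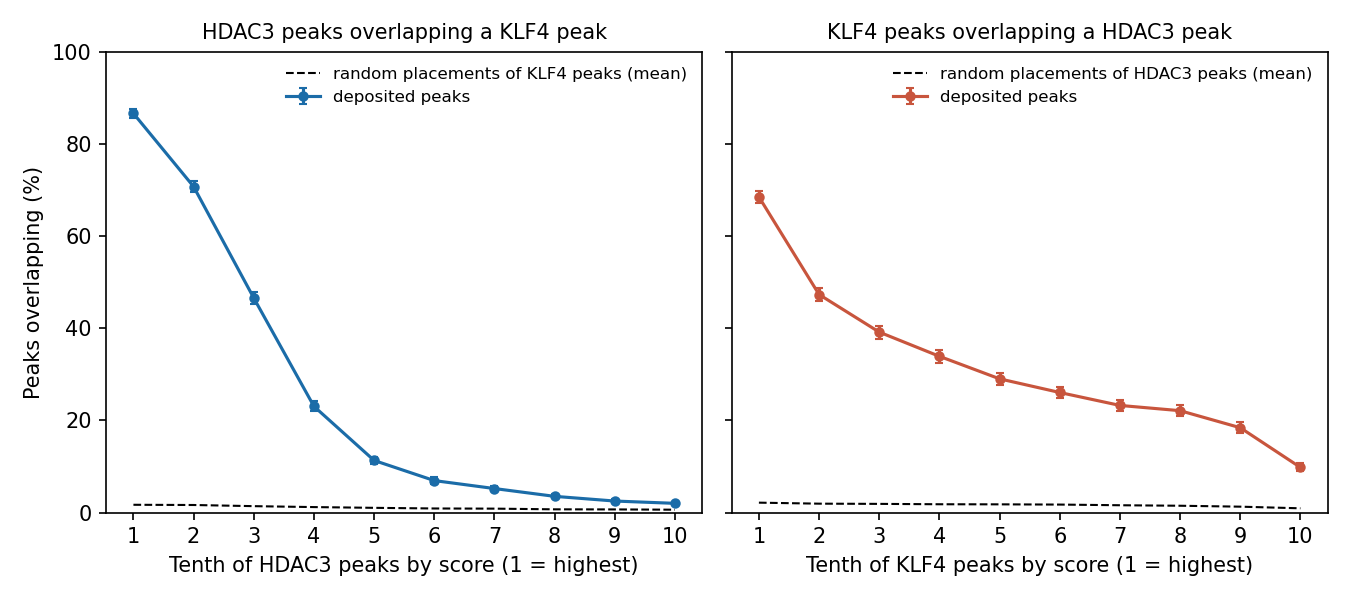
Share of peaks that overlap a peak of the other factor (vertical axis, percent) by score decile within each list (horizontal axis, 1 is the highest), with HDAC3 peaks on the left and KLF4 peaks on the right. Points are the deposited peaks, bars their exact 95% intervals (counting error only) and dashed lines the mean of random placements; the share falls from 86.6% to 2.0% for HDAC3 and from 68.5% to 9.80% for KLF4.

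Shared peaks were accordingly the higher peaks of either list. HDAC3 peaks that overlapped a KLF4 peak had a median score of 43, against 20 for the others, and the shared peak scored higher in 89.9% of all pairs of a shared and an unshared peak (89.5 to 90.2). KLF4 peaks that overlapped an HDAC3 peak had a median score of 93 against 56, and the shared peak scored higher in 69.9% of pairs (69.4 to 70.5). Across the 14967 overlapping pairs, unplaced contigs included, the scores of both factors had a Spearman correlation of 0.718. That correlation is across peaks, which are not independent replicates, and the peaks entering it had been selected by both callings.

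Strong HDAC3 peaks without a KLF4 peak formed a minority: 778 of the 5794 peaks in the highest decile. Noncoding genes were not considered in naming the gene nearest to each of them. The highest of these peaks scored 189 and lay at chromosome 19, 5845292 to 5845476, with the centre of the nearest KLF4 peak 209 bp away. Its nearest protein-coding gene was Frmd8, and it lay 5590 bp outside that gene. The next, of score 186, lay 18731 bp outside Fos, the immediate early AP-1 gene, at chromosome 12, 85455067 to 85455251, 2725 bp from the nearest KLF4 peak. Further ones lay inside Sos2 (score 159) and 11519 bp outside Fosb, another AP-1 gene (score 150, chromosome 7, 19321545 to 19321729).

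At the level of genes, the question was which promoters and other gene ends carried both factors. An HDAC3 peak lay within 1 kb of an end of 4143 of 21887 protein-coding genes (18.9%), a KLF4 peak at 5051 (23.1%), and both at 2250. Genes with an HDAC3 peak alone numbered 1893 and genes with a KLF4 peak alone 2801. Independent placement of the 4143 and 5051 genes would leave 956 with both, and no other rotation of one set along the gene order gave more than 1370. By Fisher's exact test the odds ratio was 6.34 (5.89 to 6.82), and it was 10.6 with the higher-scored 50% of each list. Neighbouring genes can share 1 peak, and the shared input described for the peak overlap applies to this count as well.

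The genes with the highest HDAC3 gene-end peaks were led by Plekha6 (score 214, 13.9-fold over input), whose peak at chromosome 1, 133162131 to 133162315, was 191 bp inside the gene and overlapped a KLF4 peak of score 620. Next came the kinase gene Vrk3 (185), Rbbp8 (174), the neighbouring aldehyde dehydrogenase genes Aldh3b2 and Aldh3b3, which shared 1 peak (169), and Cldn4, a tight junction claudin (161). The Cldn4 peak, at chromosome 5, 134946933 to 134947117 and 91 bp outside the gene, was 114-fold over input and overlapped a KLF4 peak of score 406. Tmc8 (152), Wipf2 (149) and Cabp4 (149) were also in the group, and each gene named here had a KLF4 gene-end peak as well.

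KLF4 gene-end peaks were highest at Tmem79 (score 717, 91.8-fold over input, chromosome 3, 88334419 to 88334603, 78 bp outside the gene), which encodes mattrin, a membrane protein of the lamellar granule secretory system. Tmem184a (693), Tmc8 (660), the recycling endosome GTPase gene Rab11a (656), the plakoglobin gene Jup (653, chromosome 11, 100398067 to 100398251), Plekha6 (620), Fam3b (614) and Tssk4 (606) followed, then Unc13d and Wbp2, which shared 1 peak (592). An HDAC3 gene-end peak accompanied each of them, with scores from 73 at Fam3b to 214 at Plekha6. Ranked on both factors together, the list held Plekha6, Tmc8, Jup, Tmem79, Aldh3b2, Aldh3b3, Rab11a and Cldn4 again, and added Card14, a regulator of NF-kB in keratinocytes (HDAC3 140, KLF4 557), and Metrnl (144 and 487).

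Which epidermal programmes carried the factors was asked with 23 gene lists that, like Fisher's exact test and the rule for naming genes, were fixed before the data were examined. The gene-end window in place of the promoter and the random lists matched on gene density were chosen later. Genes of the cornified envelope and late differentiation, the proteins that are cross-linked into the dead outer layers, stood out for both factors. Of 39 such genes, 25 (64.1%) had an HDAC3 gene-end peak, 22 (56.4%) a KLF4 peak, 20 both and 12 neither. Krtdap, a secreted differentiation protein, had peaks of score 125 for HDAC3 and 503 for KLF4; the envelope scaffold gene Evpl had 81 and 282, the cross-linking enzyme gene Tgm1 92 and 293, the envelope precursor Ivl 74 and 95, and the filaggrin gene Flg 35 and 85. Cnfn and Ppl lacked gene-end peaks but had peaks of both factors 2941 and 4141 bp outside the gene for HDAC3 and within 35 bp of these for KLF4. Against all other protein-coding genes, the odds ratio was 7.69 (3.97 to 14.4) for HDAC3 and 4.33 (2.30 to 8.04) for KLF4 (Fisher's exact test, two-sided, adjusted p = 3.4e-08 and 8.3e-05 by Benjamini-Hochberg over the 46 tests of all lists and both factors).

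Junction genes, whose products seal and anchor keratinocytes to each other, also carried both factors. Of 26 genes, 12 (46.2%) had an HDAC3 gene-end peak and 14 (53.8%) a KLF4 peak, 10 of them both. Cldn4 and Jup led the group, and the adhesion genes Pkp1 and Cdh1 had none at their ends but peaks further off. The highest scored 126 for HDAC3 and 538 for KLF4 at Pkp1, and 136 and 356 at Cdh1. In both genes the highest peaks of the 2 factors were different sites, and the HDAC3 peak overlapped another KLF4 peak. The odds ratios were 3.68 (1.73 to 7.89) for HDAC3 and 3.90 (1.82 to 8.26) for KLF4, with adjusted p = 0.0072 and 0.0050 by Fisher's exact test.

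Barrier lipid genes, which make and transport the ceramides and fatty acids of the outer skin, were occupied by KLF4 in 19 of 30 cases (63.3%) and by HDAC3 in 12 (40.0%), with 10 carrying both. The glucosylceramide synthase gene Ugcg had peaks of score 50 for HDAC3 and 214 for KLF4, and the ichthyosis gene Sdr9c7 57 and 221. Cyp4f39 had a KLF4 peak of score 100 at its end and stronger peaks 2476 bp inside the gene for HDAC3 (141) and 2497 bp inside for KLF4 (590), and Cers3, a ceramide synthase gene, had its peaks 10393 bp inside for HDAC3 (142) and 10416 bp inside for KLF4 (438). The KLF4 odds ratio was 5.78 (2.73 to 11.8; adjusted p = 4.4e-05) and the HDAC3 odds ratio 2.86 (1.41 to 5.95; adjusted p = 0.030), both by Fisher's exact test. The HDAC3 call was lost against random lists matched on gene density (permutation, adjusted p = 0.051) and with peaks at least 8-fold over input (odds ratio 0.985).

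**Figure D2:**
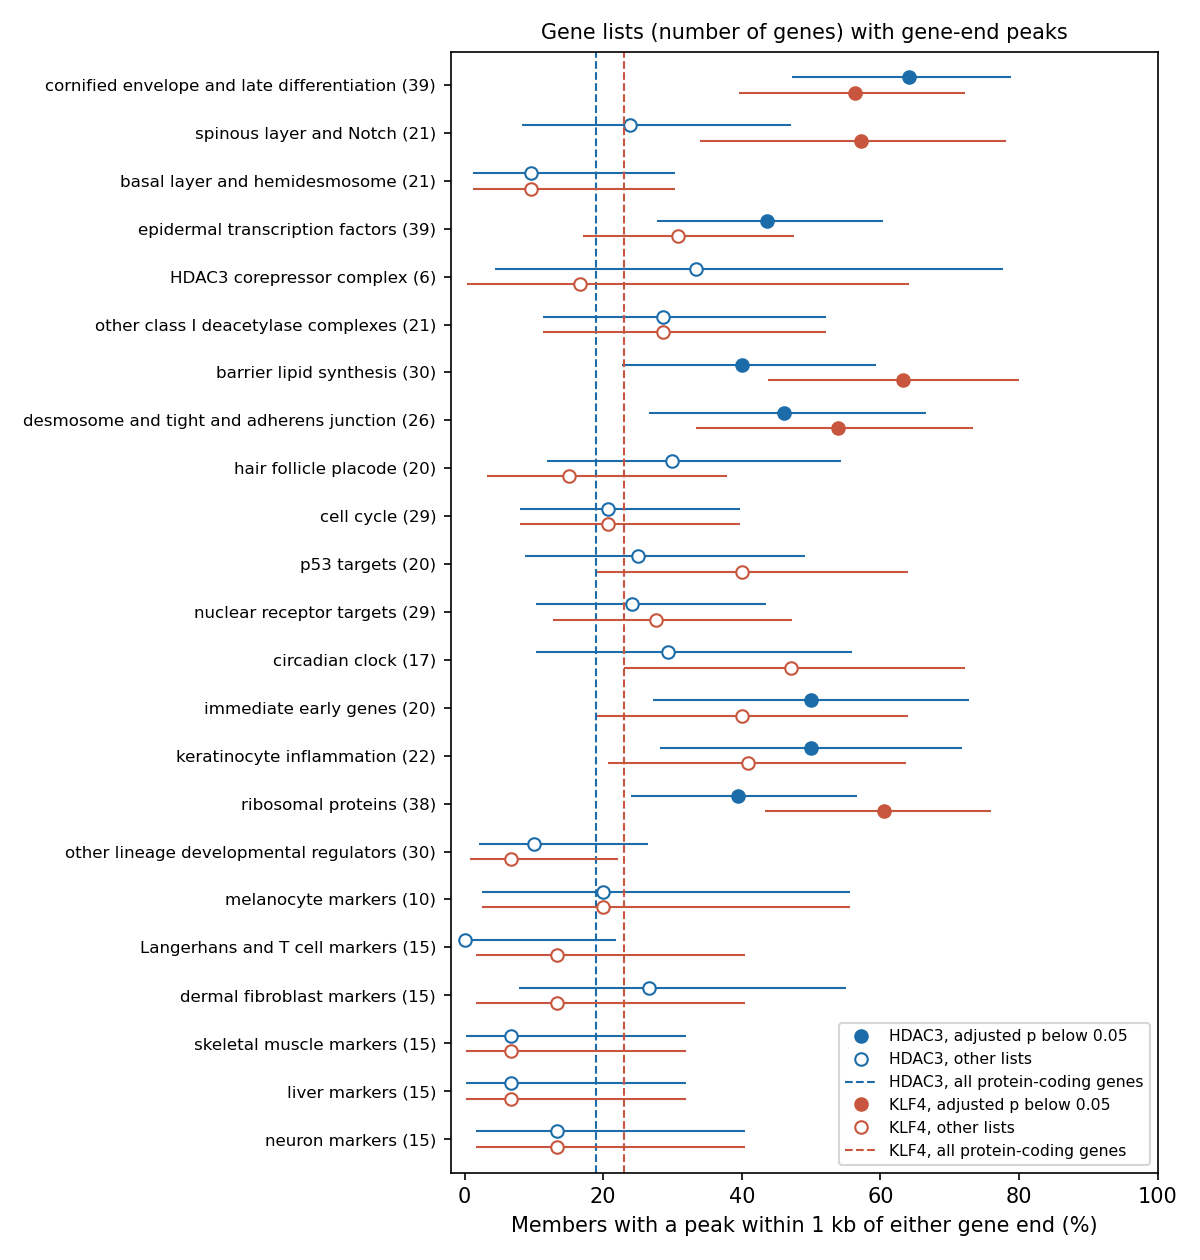
Share of each list's genes with a peak within 1 kb of either gene end (horizontal axis, percent), for HDAC3 and KLF4, with the number of genes in brackets. Points are shares, bars exact 95% intervals (counting error only), filled points lists with an adjusted p below 0.05 (Fisher's exact test) and dashed lines all protein-coding genes (18.9% for HDAC3, 23.1% for KLF4); the cornified envelope list stands at 64.1% for HDAC3 and 56.4% for KLF4.

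Genes of the spinous layer and of Notch signalling, which act as keratinocytes leave the basal layer, carried KLF4 gene-end peaks in 12 of 21 cases (57.1%) and HDAC3 peaks in 5. The suprabasal keratin genes Krt1 and Krt10 had KLF4 peaks at their ends, of score 96 and 202, and no HDAC3 peak there; likewise the transcription factor gene Ovol1 (171) and the Notch target Hes1 (77). Notch2 had both (HDAC3 68, KLF4 92). The KLF4 odds ratio was 4.45 (1.89 to 10.2; adjusted p = 0.0052) and the HDAC3 odds ratio 1.34 (0.544 to 3.75; adjusted p = 0.69), both by Fisher's exact test. HDAC3 passed with wider windows: 18 of 21 genes had an HDAC3 peak within 5 kb (odds ratio 7.01, adjusted p = 0.0015) and 20 with any peak nearest to the gene (odds ratio 10.9, adjusted p = 0.0070), by Fisher's exact test. Of all protein-coding genes, 46.2% had an HDAC3 peak and 46.0% a KLF4 peak within 5 kb. With any nearest peak these shares were 64.8% and 59.2%. A gene far from its neighbours is nearest to more sequence, and these wider settings were not matched on the space around a gene. The difference between the factors was not tested for this or any other list.

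Basal layer and hemidesmosome genes had few gene-end peaks, 2 of 21 for HDAC3 and 2 of 21 for KLF4, and neither share passed the test (odds ratio 0.451, adjusted p = 0.62, and 0.351, adjusted p = 0.47, Fisher's exact test). Cdh3 carried both factors at its end (36 and 34) besides the strong pair outside it. Lama3, Krt14 and Itga3 had peaks only away from their ends. When any peak nearest to a gene counted, the direction turned: 19 of the 21 genes had an HDAC3 peak (odds ratio 5.17) and 20 a KLF4 peak (odds ratio 13.8). Under that rule 64.8% of all protein-coding genes had an HDAC3 peak and 59.2% a KLF4 peak.

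Transcription factor genes of the epidermis carried HDAC3 gene-end peaks in 17 of 39 cases (43.6%) and KLF4 peaks in 12, with 9 carrying both. Zfp750, a regulator of terminal differentiation, had peaks of score 75 for HDAC3 and 142 for KLF4 at its end. Of genes chosen after their values were seen, Hopx had 119 and 312, Grhl2 109 and 190 and Elf3 96 and 337. Prdm1 had its strongest peaks 8947 bp outside the gene for HDAC3 (179) and 8970 bp outside for KLF4 (528), and those of Maf were 377119 bp away for HDAC3 (164) and 377131 bp away for KLF4 (183). The HDAC3 odds ratio was 3.32 (1.79 to 6.24; adjusted p = 0.0033) and the KLF4 odds ratio 1.48 (0.776 to 2.96; adjusted p = 0.49), both by Fisher's exact test. KLF4 passed within 5 kb (29 of 39 genes, odds ratio 3.41, adjusted p = 0.0021) and with any peak nearest to the gene (39 of 39, odds ratio 54.6, adjusted p = 7.1e-08), by Fisher's exact test. Of all protein-coding genes, 46.0% had a KLF4 peak within 5 kb and 59.2% were the nearest gene of one.

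Immediate early genes and genes of keratinocyte inflammation, which respond to growth factors, stress and wounding, passed the test for HDAC3. Of 20 immediate early genes, 10 had an HDAC3 gene-end peak and 8 a KLF4 peak, the latter all among those with HDAC3. Scores were 129 for HDAC3 and 237 for KLF4 at Fos, 114 and 136 at Jun, and 105 and 138 at Atf3, and Fosl2 had HDAC3 alone (85). Of 22 inflammation genes, 11 had HDAC3 and 9 KLF4, with 129 and 334 at Stat3, 109 and 90 at the chemokine gene Ccl20 and 85 and 112 at Nfkbia, the gene of an NF-kB inhibitor. The HDAC3 odds ratios were 4.29 (1.82 to 10.1; adjusted p = 0.0077) for immediate early genes and 4.29 (1.89 to 9.72; adjusted p = 0.0056) for inflammation, and those of KLF4 2.22 (0.949 to 5.42; adjusted p = 0.27) and 2.31 (1.02 to 5.39; adjusted p = 0.22), all by Fisher's exact test. With any peak nearest to a gene, the inflammation call for HDAC3 was lost (Fisher's exact test, adjusted p = 0.075) and KLF4 passed for both lists (odds ratio 4.37, adjusted p = 0.021 for inflammation; 6.21, adjusted p = 0.013 for immediate early genes). KLF4 also passed for immediate early genes within 5 kb (odds ratio 3.52, adjusted p = 0.031, Fisher's exact test), for both lists in the higher-scored 50% of peaks, and for inflammation at 8-fold over input.

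Ribosomal protein genes, a group with no particular tie to skin, carried KLF4 gene-end peaks in 23 of 38 cases (60.5%) and HDAC3 peaks in 15 (39.5%), with 13 carrying both. Rpl18 had peaks of score 99 for HDAC3 and 430 for KLF4, Rpl3 119 and 113, and Rpl38 56 and 85. The KLF4 odds ratio was 5.13 (2.67 to 9.64; adjusted p = 1.9e-05) and the HDAC3 odds ratio 2.80 (1.49 to 5.38; adjusted p = 0.012), both by Fisher's exact test. Against lists matched on gene density the HDAC3 call was lost (permutation, adjusted p = 0.051), and with any peak nearest to a gene both calls were lost (odds ratio 0.833 for HDAC3, and adjusted p = 0.059 by Fisher's exact test for KLF4).

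With a 1 kb window, the remaining lists did not pass the test for either factor, with adjusted p from 0.11 to 1 by Fisher's exact test. The corepressor complex of HDAC3 had HDAC3 peaks at 2 of 6 genes, Tbl1x (86) and Gps2 (51), and a KLF4 peak at 1, Gps2 (53). Other class I deacetylase complexes had 6 of 21 for HDAC3 and 6 for KLF4, among them Ing1 with both (49 and 63). Hair follicle placode genes had 6 of 20 and 3, among them Sox9 with HDAC3 alone (63), Lef1 with HDAC3 alone (21) and Ptch1 with KLF4 (78), whose overlapping HDAC3 peak was centred beyond 1 kb. With any peak nearest to a gene, all 20 placode genes had a KLF4 peak, against 59.2% of all protein-coding genes. The KLF4 odds ratio turned from 0.588 to 28.3. The HDAC3 test passed as well (odds ratio 10.3, adjusted p = 0.0098, Fisher's exact test), and also at 8-fold over input. Cell cycle genes had 6 of 29 for each factor, including Birc5 with HDAC3 (38). Targets of p53 had 5 of 20 for HDAC3 and 8 for KLF4, among them Sesn2 with both (97 and 152). Nuclear receptor targets had 7 of 29 and 8, and Rxra and Mylip were among those with distant peaks only. Circadian clock genes had 5 of 17 and 8 (KLF4 odds ratio 2.97, Fisher's exact p = 0.037, adjusted p = 0.12), with KLF4 at Per1 (194). Within 5 kb, KLF4 passed by Fisher's exact test for circadian clock genes (odds ratio 8.80, adjusted p = 0.0019), p53 targets (4.70, adjusted p = 0.0084) and nuclear receptor targets (2.61, adjusted p = 0.036). With any peak nearest to the gene, KLF4 passed for the same lists (5.17, 3.91 and 19.3, in that order), and HDAC3 for nuclear receptor targets (15.2) and other class I deacetylase complexes (5.17).

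Genes of most other lineages carried few gene-end peaks. Developmental regulators of other lineages had HDAC3 gene-end peaks in 3 of 30 cases and KLF4 peaks in 2, Hoxc13 with both (33 and 54); the KLF4 odds ratio was 0.238 (0.0801 to 1.06; adjusted p = 0.11, Fisher's exact test) and passed the test within 5 kb (odds ratio 0.180, adjusted p = 0.0016). Markers of cell types that an epidermal preparation could hold besides keratinocytes were scored for the same peaks. Melanocyte markers had 2 of 10 for each factor, both at Pmel (34 and 84). Langerhans and T cell markers had 0 of 15 for HDAC3, which allows a share of up to 21.8% by the exact interval, and 2 for KLF4. Dermal fibroblast markers had 4 of 15 for HDAC3, with scores from 18 at Postn to 23 at Twist2, and 2 for KLF4, at Col1a1 (236) and Thy1 (130). Skeletal muscle markers had 1 of 15 for each, Tnni2 with HDAC3 (27) and Mylpf with KLF4 (90). Liver markers had 1 of 15 for each. Neuron markers had 2 of 15 for each, with both at Syt1 (23 and 52). None of these marker shares passed the adjusted threshold for either factor with the 1 kb window. Liver markers passed as depleted of KLF4 within 5 kb (1 of 15, odds ratio 0.0837, adjusted p = 0.0052) and with any peak nearest to the gene (0.172, adjusted p = 0.0084), by Fisher's exact test.

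A group of regulators and layer markers was examined whether or not it carried peaks. Hdac3 itself and the basal keratin gene Krt5 had no peak of either factor at their ends and were the nearest gene of none. The corepressor gene Ncor1 had none at its ends and was the nearest gene of 6 HDAC3 and 2 KLF4 peaks. Klf4 had an HDAC3 peak of score 58 located 981 bp outside one end and no KLF4 peak within 1 kb, yet it was the nearest gene of 53 HDAC3 and 56 KLF4 peaks. Trp63, the master regulator of stratified epithelia, and Grhl3, a regulator of barrier formation, had no gene-end peaks. The highest Trp63 peaks lay inside the gene on chromosome 16. They were at 25758207 to 25758391 and 74536 bp from an end for HDAC3 (73), and 74527 bp from it for KLF4 (204). The highest Grhl3 peaks were at different sites, 2000 bp outside the gene for HDAC3 (100) and 24745 bp outside for KLF4 (281). The basal keratin gene Krt14 had 1 HDAC3 and 7 KLF4 peaks nearest to it, the highest 14607 and 12017 bp outside (97 and 346). An HDAC3 peak of score 139 at chromosome 15, 101835037 to 101835221, lay 10297 bp outside Krt1 and overlapped a KLF4 peak of score 391.

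The epidermal differentiation complex, the chromosome 3 region that holds the loricrin, involucrin, small proline-rich, late cornified envelope, filaggrin and S100 genes, was mapped as a region chosen after the lists had been examined. From S100a1 to S100a11 (90511034 to 93526288, 69 protein-coding genes) it held 173 HDAC3 peaks and 166 KLF4 peaks. Per Mb these were 57.4 and 55.1 peaks, 2.68 and 3.16 times the density of the genome. Both numbers lay within the range of random placements at protein-coding gene ends, which follow the density of genes (149 to 228 for HDAC3 and 112 to 195 for KLF4). Of these peaks 83 overlapped, which is 48.0% of those of HDAC3 and 50% of those of KLF4. The highest HDAC3 peak scored 122 (92494009 to 92494193) and overlapped a KLF4 peak, and the highest KLF4 peak scored 509 (90525512 to 90525696), lay 1023 bp outside S100a13 and did not overlap an HDAC3 peak. Ivl had its HDAC3 peak at 92573753 to 92573937, 55 bp outside the gene.

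**Figure D3:**
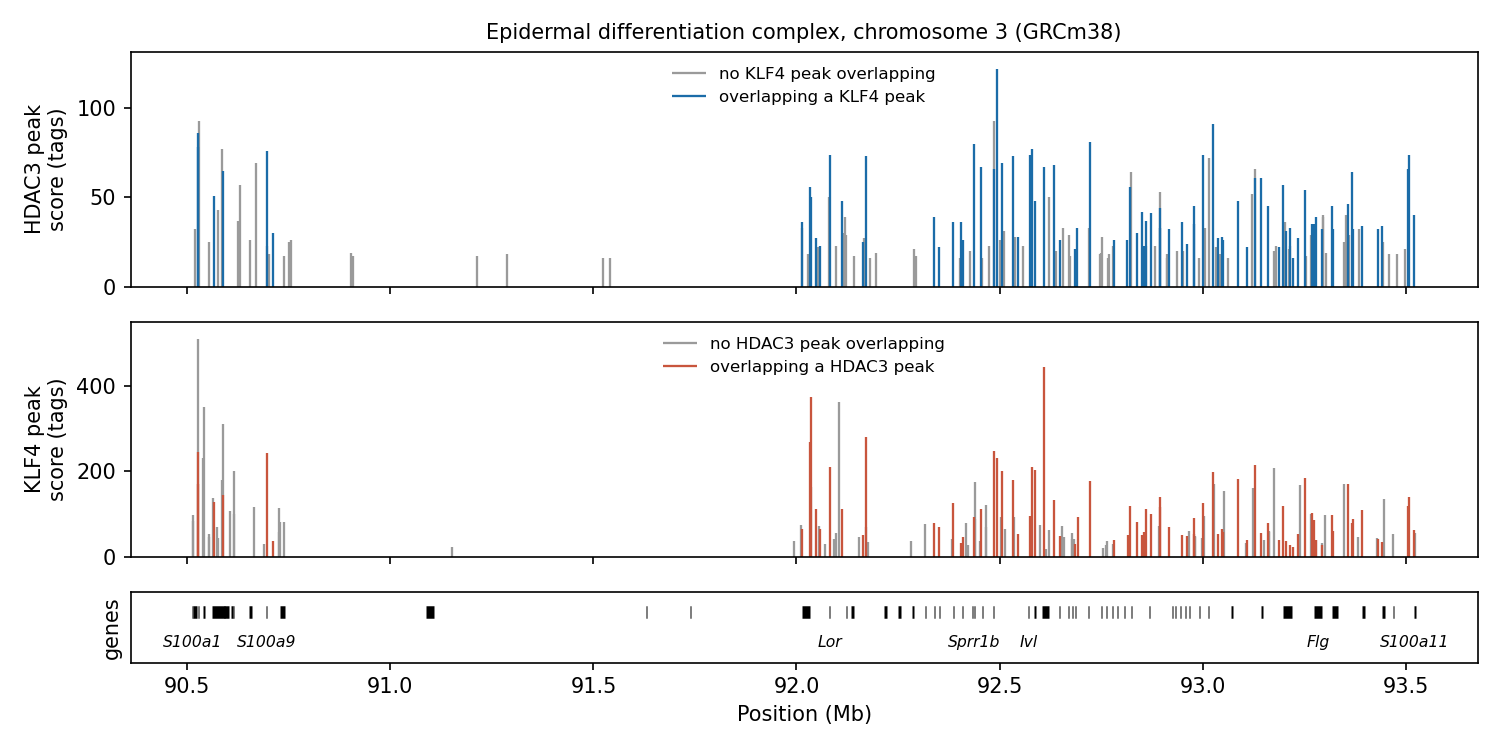
Peaks of HDAC3 (top) and KLF4 (middle) across the epidermal differentiation complex, by position (horizontal axis, Mb, GRCm38 chromosome 3) and score (vertical axis, tags), with coloured lines for peaks that overlap a peak of the other factor and grey lines for the others. The bottom track shows protein-coding genes; 83 of the 173 HDAC3 and 166 KLF4 peaks overlap.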

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

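Of the tests in this part, the input level of the lowest HDAC3 decile and the direct comparison of ribosomal protein genes with other housekeeping genes were chosen after the result was seen, as was the restriction to peaks that pass at 3 times the expected input.

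Peaks on unplaced contigs were left out of the comparisons with genes, and microRNA genes were not examined as a class in the report. Unplaced contigs held 16 HDAC3 peaks on 12 contigs and 15 KLF4 peaks on 8 contigs; 7 contigs had both, and 5 of the HDAC3 peaks overlapped a KLF4 peak. Among 1228 microRNA genes, 102 had an HDAC3 peak within 1 kb of an end, fewer than in any of 200 placements (mean 128, range 104 to 154), and 102 had a KLF4 peak, within the range of placements (mean 111, 87 to 144). The placements move each peak on its own and lose the clustering of real peaks, so the lower HDAC3 number cannot show depletion at microRNA genes. Both factors were at 41 of the microRNA genes.

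Overlap with KLF4 fell from 86.6% in the highest to 2.0% in the lowest HDAC3 score decile. Whether the lowest peaks are sites in the wider neighbourhood of KLF4-bound regions is not decided. In the lowest decile, 5.71% had a highest-decile KLF4 peak 10 to 50 kb away and none nearer. The placement mean was 16.3% (highest 18.1%). The placements move each peak on its own and lose the clustering of real peaks, so a lower observed share cannot decide it. Selection of the lowest peaks on chance lows of the input stays open: they held on average 1.36 input tags, below the 2.57 of an even spread, but the 4-fold rule admits a mean of at most 2.19 there, so the calling fixed that outcome and the test decides nothing. That HDAC3 occupies sites of its own with weak signal was not tested, since 1 library cannot tell weak binding from background.

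High HDAC3 peaks overlapped KLF4 peaks far more than placements did. A cut on tags argues against the shared input as the whole cause. Among peaks whose tags would pass the 4-fold rule at 3 times the expected input, 78.3% of HDAC3 peaks overlapped a KLF4 peak, and no placement exceeded 1.25%. Of KLF4 peaks under that cut, 24.7% overlapped an HDAC3 peak, against 31.7% for the whole list, and no placement exceeded 0.380%. The expected input is that of an even spread, which the input did not follow, so the cut does not exclude a part played by the input. Open chromatin that yields tags in any precipitation cannot be told apart from joint binding. Within score deciles, shared HDAC3 peaks differed from unshared ones by -0.125 input tags (largest absolute value of 1000 shuffles 0.068), the opposite of what open regions would give, but shared peaks still averaged 4.11 input tags against 2.57 for an even spread, and both callings had removed sites with a high input. A library with a non-specific antibody was not analysed here, and joint binding of both proteins may or may not underlie the overlap.

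Ribosomal protein genes carried KLF4 gene-end peaks with an odds ratio of 5.13 (2.67 to 9.64). Ends of active housekeeping genes in general could contribute: proteasome, complex I and initiation factor genes had an odds ratio of 2.31 (1.64 to 3.26; 55 of 135 genes), and ribosomal protein genes exceeded them by an odds ratio of 2.23 (1.06 to 4.55; Fisher's exact p = 0.042), so the intervals overlap while the direct test narrowly passes. Tags shared with pseudogene copies are not excluded either: 4.40% of ribosomal protein pseudogenes (14 of 318) and 3.43% of other pseudogenes (353 of 10291) had a KLF4 peak (Fisher's exact p = 0.35). Regulation of these genes by KLF4 was not tested, because no expression values were analysed here.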

How the results depend on the processing

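The comparisons with the 10000 highest peaks, with 3 times the expected input, with rotated lists and with density-matched lists were chosen after the result was seen; the others were not. The overlap of HDAC3 and KLF4 peaks exceeded every placement under all 7 alternatives run for each list, with ratios to the placement mean from 36.5 to 133 for HDAC3 and 30.2 to 125 for KLF4. The odds ratio across genes ranged from 4.97 (5 kb) to 10.6. Shares at gene ends moved with the peaks and the definition: 15.2% and 17.7% (HDAC3 and KLF4) in the higher-scored 50% of each list, 10.1% and 14.2% at 8-fold over input, 33.6% and 40.9% within 5 kb, and 6.97% and 10.8% for protein-coding ends. With centres within 100 bp, the shared KLF4 peak scored higher in 70.9% of pairs.

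The number of lists called for KLF4 rose from 5 to 12 within 5 kb, all 5 kept, and to 13 with any nearest peak, 4 of the 5 kept; the cause was not tested. For HDAC3 the number stayed between 5 and 10. The direction reversed for basal genes with any nearest peak (odds ratio 5.17 for HDAC3, 13.8 for KLF4), for placode genes and KLF4 (28.3), for ribosomal protein genes and HDAC3 (0.833), and for barrier lipid genes and HDAC3 at 8-fold over input (0.985, 2 genes with a peak); the cause was not tested. Of the 46 odds ratios, 46 kept their call with rotated lists, 44 with density-matched lists (2 weaker), 44 with the higher-scored 50% (2 newly past it), 43 at 8-fold, 38 within 5 kb (8 newly past it) and 29 with any nearest peak (11 newly past it, 2 weaker). A direction was counted as reversed only where the list was called under at least 1 of the settings compared; some uncalled odds ratios also crossed 1, such as basal genes within 5 kb (1.56 for HDAC3 and 1.56 for KLF4). Of 238 scores of named genes, 9 moved with the higher-scored 50%, 30 at 8-fold, 99 within 5 kb and 175 with any nearest peak. Motif alternatives and lists matched on GC content were not run, and no paired analysis was possible because each antibody had 1 library.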

Other observations

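The keratin clusters, the genes beside the most peaks, the microRNA genes and the test at immediate early genes were all chosen after the result was seen.

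Both keratin clusters held more peaks per Mb than the genome and, except for KLF4 in the type II cluster, fewer than random placements at gene ends, which follow the density of genes. The placements move each peak on its own and load regions of packed gene ends, with a mean of 160 HDAC3 peaks in the type I cluster. A number below them therefore cannot show depletion. The type I cluster on chromosome 11 (99232761 to 100145926, 60 protein-coding genes) had 55 HDAC3 peaks and 50 KLF4 peaks, below the lowest of the random placements for each factor (122 and 94) and 2.81 and 3.14 times the density of the genome. Of the HDAC3 peaks there, 17 belonged to the highest score decile and 23 overlapped a KLF4 peak. The type II cluster on chromosome 15 (101348315 to 102032026, 27 genes) had 30 HDAC3 peaks, again below the lowest placement (48), and 43 KLF4 peaks, within the range of placements (38 to 82); these were 2.05 and 3.61 times the density of the genome. Of its 30 HDAC3 peaks, 17 were in the highest decile and 19 overlapped a KLF4 peak.

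Several genes stood beside long runs of peaks of both factors. Epha4, an ephrin receptor gene, was the nearest gene of 73 HDAC3 and 58 KLF4 peaks, Gata3, a regulator of epidermal and hair follicle fate, of 61 and 56, and Myc of 64 and 43. These counts were spread over 1.34 Mb at Epha4, 1.27 Mb at Gata3 and 1.43 Mb at Myc. For HDAC3 and KLF4 the densities were 2.53 and 2.47 times the genome's at Epha4, 2.23 and 2.52 at Gata3 and 2.09 and 1.72 at Myc. Around Klf4 the density was 78.3 HDAC3 peaks and 82.8 KLF4 peaks per Mb over 0.677 Mb, which is 3.66 and 4.75 times the genome's. Tle3, a Groucho-type corepressor gene, had the most KLF4 peaks, 59 over 0.540 Mb (6.27 times the genome's density), and 33 HDAC3 peaks. Near Mir203, a microRNA of differentiating keratinocytes, overlapping peaks of score 113 for HDAC3 and 285 for KLF4 lay at chromosome 12, 112125954 to 112126138 for HDAC3, 4834 bp from the gene. Mir205 had a KLF4 peak of score 207 within 10 kb and no HDAC3 peak, and the Mir200a, Mir200b and Mir429 cluster had a KLF4 peak of score 165 and none of HDAC3. Mir21a had both (96 and 120).

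Because strong HDAC3 peaks without KLF4 included sites near Fos and Fosb, a hypothesis was that HDAC3 sites without KLF4 may lie preferentially at immediate early genes. In the highest HDAC3 decile, an immediate early gene was the nearest gene of 13 of 778 peaks without KLF4 (10 distinct genes) and 55 of 5016 peaks with it. The odds ratio was 1.53 (0.866 to 2.87; Fisher's exact p = 0.21, adjusted p = 0.79 over all lists), too imprecise to decide. Hair follicle placode genes had the highest odds ratio among lists with at least 5 peaks without KLF4, 3.25 (1.46 to 7.67; Fisher's exact p = 0.010, adjusted p = 0.24), which fails the correction, and peaks beside 1 gene are not independent.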
